A study of Homo sapiens with 14 samples.

How the data were processed

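NanoString probe signals were analysed for CD4 T cells from 3 asthmatic and 4 healthy donors. Per the labels, the cells of each donor were cultured for 7 days without or with exosomes from the same donor's bronchoalveolar lavage fluid, at 10 exosomes per T cell. The medium was RPMI with L-glutamine, human AB serum depleted of exosomes, and a supplement at 50 IU per ml whose name the label omits. RNA was isolated with a PureLink kit, per the labels. Each culture gave 1 library, so the replicates were separate donors and the 14 libraries formed 7 pairs. The cultures of healthy donor 2 were read in different runs, so the change with exosomes in that pair is confounded with the run. Per the labels, 7 libraries were read in a first run, 2 in another, and 1 in a further run. The labels of the remaining 4 libraries, those of asthmatic donor 3 and healthy donor 4, named no run.

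The deposited values were normalized signal on a linear scale for 77 genes, beside 6 positive and 8 negative control probes listed as whole numbers. Per the series' design text, TUBB and RPL19 served the authors as housekeeping genes, and healthy cultures without exosomes were the control. The software, the use of the positive controls and any background treatment were not given in the sources used here. In each library, 100% of the gene values above the lowest listed value of 1 were whole multiples of a single step, within 0.05 of a step. The deposited signal was therefore treated as a count times 1 factor per library, with values under 1 listed as 1. The step, which is the signal of 1 count, ran from 0.483 to 129.6, and the total count per library from 2425 to 128306. The geometric mean of TUBB and RPL19 ran from 3519 to 5069 over the 14 libraries. A gene was called above background where its count exceeded the mean of the negative probes plus 2 SD in the same library. The counts limited the precision of low signals, and the Poisson interval given for a single count covers counting error only.

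Gene names were matched to the reference table of human genes. Of the 77 names, 52 were current symbols and 18 were synonyms of a single gene. AMPK and NRF2 each matched several genes. PFK2 was a synonym of PFKFB3, which had its own probe. IL23, PI3KA, PI3KD and PI3KG matched none. All are written as deposited, including GLUT1, IL17, RORG, ERRA, PGC1A and LKB1.

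Signals were transformed as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3. The effect of exosomes was estimated in asthmatic donors, in healthy donors, as the difference between these effects, and over all donors, each with donor as a fixed block. These fits used all 14 libraries, and both donor groups shared 1 moderated estimate of the spread per gene. The SEs given for asthmatic or healthy donors therefore do not measure the spread of that group's pairs alone. Asthmatic and healthy donors were compared without exosomes, with exosomes, and as treated asthmatic against untreated healthy cultures, with 1 library per donor. All limma tests were two-sided, with Benjamini-Hochberg adjustment over 77 genes and a threshold of 0.05. The pairing of libraries was taken from the labels. The correlation over genes between a donor's libraries, after subtraction of the group means, was 0.730 to 0.951 over the 7 donors. It was not computed in this way between libraries of different donors, so it cannot test the pairing. Exact two-sided tests enumerated 128 sign patterns of the 7 pairs, or 35 divisions of the donors into 3 and 4. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

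The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took genes past the threshold. It then added, up to 20 in all, the genes with the largest absolute log2 change among those that moved the same way in every pair, or whose donor groups did not overlap, leaving out the lowest 25% of genes by mean. The lineage genes TBX21, GATA3, RORG, FOXP3, IFNG, IL4, IL5, IL13, IL17 and IL10 and the mitochondrial genes ERRA, PGC1A and SIRT1 were named in every comparison. Other genes named were chosen after their values were seen. Of 25 lists, 10 had at least 3 measured members and were tested with fry and camera from limma. These were Th1, Th2, Th17, Treg, glycolysis and glucose uptake, mitochondrial biogenesis and dynamics, fatty acid oxidation and lipid metabolism, mTOR, AMPK and PI3K signalling, cytokine and JAK-STAT signalling, and reference genes. Lists for activation, follicular helper cells, redox and interferon responses had fewer than 3 measured genes. Lists for T cell identity, naive and memory cells, mitochondrial respiration, mitophagy, cell death and chemokines had 0. The 5 marker lists for other cell types (myeloid, B, CD8 T and NK, epithelial, and granulocyte and mast cells) also had 0 measured genes, so the purity of the cells could not be examined with them. PU.1 and NOX2, which myeloid cells also express, were measured but were not in these lists. PU.1 was above background in 3 untreated and 3 treated healthy libraries and in 0 asthmatic ones. NOX2 was above background in 3 and 3 healthy and in 2 untreated and 1 treated asthmatic libraries. Whether other cells were present was not tested.

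The tests were run on simulated data with the fitted means and residual SD of each gene, over 50 panels in which 20 of 77 genes were changed. The simulated noise was normal, equal in all libraries and independent between genes, with no floor at 1 count. The libraries here differ in these respects, so the shares recovered need not hold for them. Of genes changed 2-fold, 58.4% were recovered for the effect of exosomes in asthmatic donors, 67.6% in healthy donors, 31.4% for the difference and 82.2% over all donors. For untreated asthmatic against healthy cultures, 0.3% of 2-fold, 9.6% of 4-fold and 48.2% of 8-fold changes were recovered. Alternatives covered pseudocounts of 0.5 and 20, filters on low values, scaling to other references, variance models, the donor block, the run as a block and leaving out each donor. All libraries and genes were kept for the results reported.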

Results

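The expression of 77 T cell and metabolic genes was measured with NanoString probes in CD4 T helper cells cultured with or without airway exosomes, the small vesicles that cells release. There were 3 asthmatic and 4 healthy donors, each with an untreated and an exosome-treated culture. The total count was 10989 to 91794 in untreated asthmatic, 48394 to 128306 in treated asthmatic, 3259 to 100762 in untreated healthy and 2425 to 116924 in treated healthy cultures. RPL19, a ribosomal protein gene, took 30.6% to 54.3% of the counts in 12 libraries. IL2, the T cell growth factor, took 59.6% and 58.1% in the untreated and treated libraries of asthmatic donor 3. Between 29 and 67 genes were above background per library, with 29 and 42 in healthy donor 4. In the untreated library of asthmatic donor 3 the negative probes were all at 1 count, so that any gene with at least 2 counts was above background there, among them IL4 with 6 and IL10 with 7 counts. The cytokine genes IL2, IL4, IL10, IL17 and IL21 were above background in 2 libraries, both of asthmatic donor 3, and PGC1A, SLC2A3 and SULT2B1 in 0 of 14.

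**Figure D1:**
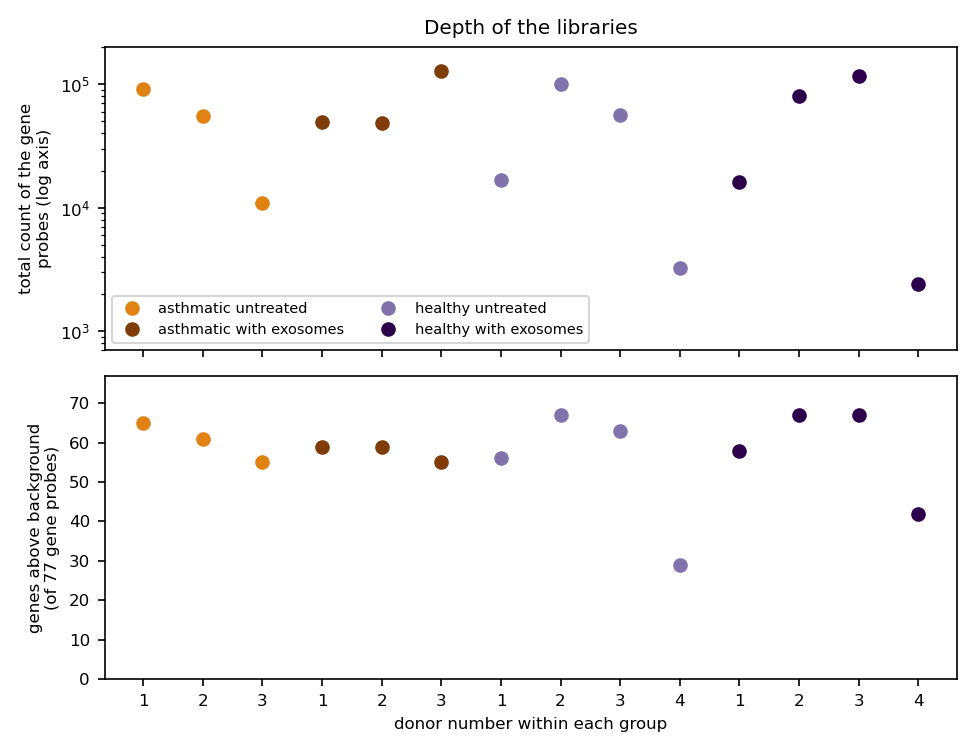
Total count of the gene probes (upper panel, log axis) and number of the 77 genes above background (lower panel) in each library, with 1 point per library, colours for the 4 groups and donor numbers on the horizontal axis. Healthy donor 4 had the lowest totals, 3259 and 2425, and 29 and 42 genes above background.

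The first question was how airway exosomes altered T cells of asthmatic donors. Signals of Th2 cytokine genes were lower in treated than in untreated cultures, without passing the test. The SEs below are those of the fit to both donor groups. IL13, which drives mucus production in the airway, had a log2 change of -0.98 (SE 0.30, n = 3 pairs), and IL5, the growth factor of eosinophils, one of -0.97 (SE 0.37), both lower in 3 of 3 donors. IL4, which directs Th2 differentiation, had a change of -1.01 (SE 0.35) and was lower in 2 of 3. The barrier cytokine gene IL22 had a change of -1.11 (SE 0.41) and IFNG, the Th1 cytokine gene, one of -0.87 (SE 0.43), both lower in 3 of 3. In asthmatic donor 2, IFNG went from 6 to 5 counts, neither above background, a change of -0.06. PFKFB3, whose product drives glycolysis, was higher in 3 of 3 donors, with a change of 0.57 (SE 0.23). With limma, 0 of 77 genes passed an adjusted p of 0.05, the smallest adjusted p was 0.372, and 8 genes had an unadjusted p under 0.05, against 3.85 expected by chance. The count at an unadjusted p under 0.05 ranged from 1 to 18 over the alternatives. In all, 25 genes moved the same way in 3 of 3 pairs, 2 higher and 23 lower, where chance gives 25%, or 19.25 genes.

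By group, 7 of 7 measured Th2 genes were lower, with a median of -0.73, against a median of -0.25 for all 77 genes. None passed the test, and the smallest p adjusted over the list alone was 0.0719. The directional fry test of the Th2 list gave an adjusted p of 0.110, fry for either direction 0.0906, and camera an adjusted p = 0.462 with an estimated correlation. With each library centred on the median gene, the fry adjusted p of this list was 0.0207, in a range of 0.0207 to 0.462 for the smallest list p over the alternatives. The Th2 regulators had smaller changes, -0.30 (SE 0.31) for GATA3 and -0.43 (SE 0.27) for c-MAF. They were at 0.17 and -0.19 without asthmatic donor 3. In the Th1 list 5 of 6 genes were lower, including TBX21, the Th1 master regulator, at -0.41 (SE 0.43) and STAT4 at -0.42 (SE 0.29). In the Th17 list 5 of 6 were lower, including AHR at -0.28 (SE 0.18) and IL17 at -0.08 (SE 0.38), while RORG was at 0.15 (SE 0.29), lower in 2 of 3 donors. Without asthmatic donor 3, where RORG had 1 count in the untreated library, it was at -0.27 and IL17 at 0.35. Of the Treg genes 3 of 5 were lower, FOXP3 at -0.06 (SE 0.44), or 0.03 without asthmatic donor 1, and IL10 at -0.39 (SE 0.48), or -0.08 without asthmatic donor 3. The fry adjusted p was 0.176 for both the Th1 and the Th17 list and 0.924 for the Treg list.

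Of the fatty acid and lipid genes 4 of 4 were lower, among them CPT1A, which carries fatty acids into mitochondria, at -1.03 (SE 0.46) and SREBP2 at -0.13 (SE 0.19). Of the mitochondrial biogenesis genes 3 of 3 were lower, ERRA at -0.45 (SE 0.37), SIRT1 at -0.26 (SE 0.20) and PGC1A, below background throughout, at -1.48 (SE 0.64). These were at -0.02, -0.10 and -0.26 without asthmatic donor 3, and PGC1A was at 1 count in both libraries of that donor, so that its change of -3.92 there was that of the signal per count. Without this donor the mTOR, AMPK and PI3K list had 2 of 6 genes lower, the JAK-STAT list 3 of 6 and the lipid list 3 of 4. Glycolysis genes divided, with 5 of 8 lower, such as PGK1 at -0.35 (SE 0.20). Of the mTOR, AMPK and PI3K genes 4 of 6 were lower, among them the energy sensor AMPK at -0.45 (SE 0.18), and 4 of 6 JAK-STAT genes were lower. The fry adjusted p was 0.176 for the lipid genes, 0.202 for the mitochondrial genes and 0.434 for each of the glycolysis, mTOR and JAK-STAT lists. In the reference list 3 of 4 genes were lower, with a median of -0.09 and a fry adjusted p of 0.202. Further genes lower in 3 of 3 donors were PI3KG at -0.66 (SE 0.34), CLTC, the clathrin heavy chain gene, at -0.43 (SE 0.25), POU2F1 at -0.42, the amino acid transporter gene SLC7A5 at -0.39, PI3KA at -0.37, ETS-1 at -0.35, DNMT1 at -0.26 and NRF2 at -0.20. Without asthmatic donor 3, CLTC was at -0.07, ETS-1 at -0.15, PGK1 at -0.21, NRF2 at -0.03 and SREBP2 at -0.06, and POU2F1, STAT4 and PI3KA were at -0.26, -0.26 and -0.24.

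IL4, IL5, IL13 and IL22 were above background in 2 of 16 values of asthmatic donors 1 and 2, and without asthmatic donor 3 the Th2 list had 5 of 7 genes lower with a median of -0.23, the median of all genes was -0.09, and the changes of CPT1A, PFKFB3, PI3KG and IL4 were -0.22, 0.31, -0.30 and -1.54. Without asthmatic donor 1 IFNG was at -0.37, and without asthmatic donor 2 IL22 was at -0.71 and TBX21 at -0.19. Leaving out 1 donor turned or moved 24 of 30 named genes by over 1.5-fold. The median of all genes was -0.36 with scaling to RPL19 alone and -0.11 with scaling to the total count without IL2, IFNG, IL17 and RPL19.

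**Figure D2:**
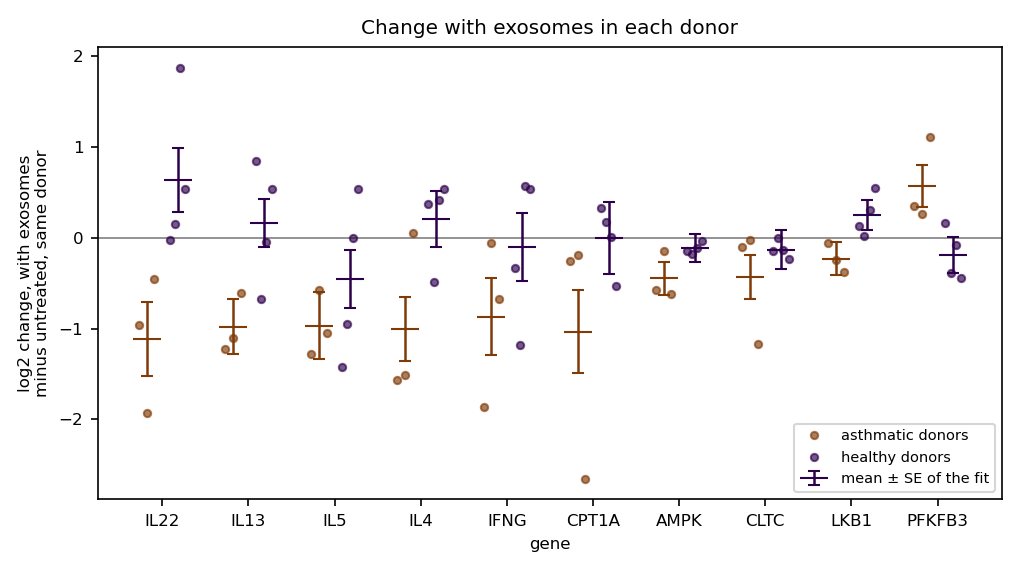
Log2 change of 10 genes (vertical axis, exosome-treated minus untreated culture of the same donor), with 1 point per donor, 3 asthmatic and 4 healthy, and bars for the fitted mean and its SE. IL22, IL13 and IL5 lay below 0 in 3 of 3 asthmatic donors with means of -1.11, -0.98 and -0.97 and PFKFB3 above 0 in 3 of 3, while AMPK and CLTC lay below 0 in 7 of 7 donors.

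The same question was asked in healthy donors. STAT5A, a mediator of IL2 signalling, was higher in 4 of 4 donors with a log2 change of 0.20 (SE 0.20, n = 4 pairs), or 0.11 without healthy donor 4. HIF1A, the oxygen-sensing transcription factor gene, was lower in 4 of 4 at -0.18 (SE 0.20), or -0.02 without healthy donor 4, as were CLTC at -0.13 (SE 0.21) and AMPK at -0.12 (SE 0.15). The cytokine genes lay on both sides of 0, with IL4 at 0.21 (SE 0.31), IL13 at 0.17 (SE 0.26), IL17 at 0.16 (SE 0.33), IL5 at -0.46 (SE 0.32), IL10 at -0.15 (SE 0.41) and IFNG at -0.10 (SE 0.37). These 6 genes were at 1 count in both libraries of healthy donor 4, so that the change of 0.54 there was that of the signal per count. Without that donor IL4, IL13, IL17, IL5, IL10 and IFNG were at 0.10, 0.04, 0.04, -0.79, -0.38 and -0.31. Among the lineage regulators, TBX21 and FOXP3 were at -0.36 each (SE 0.37 and 0.38), RORG at -0.23 (SE 0.25) and GATA3 at -0.04 (SE 0.27). The mitochondrial genes ERRA, SIRT1 and PGC1A were at -0.10, 0.02 and 0.13. PGC1A was also at 1 count in both libraries of healthy donor 4, with the same change of 0.54. In healthy donors 1 to 3 its changes were -0.02, 0 and 0. Leaving out 1 donor turned the direction of 10 of 17 named genes and turned or moved 15 by over 1.5-fold. Without healthy donor 4, in which both fell to 1 count, TBX21 was at 0.10 and FOXP3 at 0.20. Without healthy donor 1, ERRA was at 0.22, IL10 at 0.41, IL13 at -0.06 and IL17 at -0.07, and without healthy donor 2, whose cultures were read in different runs, IFNG was at 0.26. With limma 0 of 77 genes passed, the smallest adjusted p was 0.980, and 0 genes had an unadjusted p under 0.05. The median change of all genes was -0.01, and the median 95% interval reached 0.58 to either side.

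Of the Th17 genes 5 of 6 were higher in healthy donors with exosomes, median 0.12, and of the JAK-STAT genes 5 of 6, median 0.11, while 4 of 7 Th2 genes were lower, median -0.04. Without healthy donor 4 the Th17 list had 4 of 6 genes higher, median 0.03, and the JAK-STAT list 3 of 6. The smallest fry adjusted p of the 10 lists was 0.999, and 0 genes passed when adjusted over the list alone. LKB1, the kinase that activates AMPK, and STAT5A were the 2 genes higher in 4 of 4 pairs, and 5 were lower, namely AMPK, CLTC, HIF1A, IL9 and SLC2A3, where chance gives 12.5%, or 9.63 genes.

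Whether exosomes acted differently on asthmatic and healthy cells was tested as the difference between their effects. Among the named genes, IL22 had a difference of -1.75 (SE 0.54, 3 against 4 donors), IL13 one of -1.15 (SE 0.40) and PI3KG one of -1.05 (SE 0.45). IL22 was above background in 3 of 14 libraries, 0 of them untreated healthy, and at 1 count in both libraries of healthy donor 4, whose 0.54 was the change in signal per count. Its difference was -2.11 to -0.15 over the alternatives, and -0.15 with every value raised to the largest step. IL4, within the lowest 25%, was at -1.21 (SE 0.47). PFKFB3 had a difference of 0.76 (SE 0.31), from 0.57 in asthmatic and -0.19 in healthy donors. IFNG was at -0.77 (SE 0.57), IL5 at -0.51 (SE 0.49), IL10 at -0.25 (SE 0.63) and IL17 at -0.24 (SE 0.50). The regulators were at 0.38 for RORG (SE 0.38), 0.30 for FOXP3 (SE 0.58), -0.26 for GATA3 (SE 0.42) and -0.05 for TBX21 (SE 0.56), and the mitochondrial genes at -0.35 for ERRA, -0.27 for SIRT1 and -1.61 for PGC1A. Leaving out 1 donor turned the direction of 7 of these 16 genes and turned or moved 13 by over 1.5-fold. Without asthmatic donor 3, RORG was at -0.04, GATA3 at 0.21, ERRA at 0.08, IL17 at 0.19 and IL10 at 0.07, and without healthy donor 4 FOXP3 was at -0.26. TBX21 was at 0.17 without asthmatic donor 2 and at 0.34 without healthy donor 1, IFNG at -0.27 without asthmatic donor 1 and IL5 at -0.18 without healthy donor 4. The differences of PI3KG, PFKFB3, SIRT1 and PGC1A were -0.70, 0.50, -0.12 and -0.39 without asthmatic donor 3. In limma none of the differences passed, 0 of 77, the smallest adjusted p was 0.588, and 6 had an unadjusted p under 0.05.

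In the Th1 list 6 of 6 genes had a negative difference, median -0.42, in the Th2 list 6 of 7, median -0.49, and in the Th17 list 5 of 6, median -0.29, against -0.24 for all genes. The Th2 list had 4 of 7 genes with a negative difference without asthmatic donor 3, median -0.25. The fry adjusted p was 0.295 for each of these, and the smallest p adjusted over the list alone was 0.0716, for IL22 in the Th17 list. The asthmatic and healthy changes did not overlap for 6 genes, IL22, LKB1, PFKFB3, PGC1A, PI3KG and SMPD1, where chance gives 5.71%, or 4.4 genes. PGC1A and SMPD1 were at 1 count in both libraries of asthmatic donor 3 and of healthy donor 4, so that their changes of -3.92 and 0.54 there were those of the signal per count. Over the 35 divisions of the donors, the exact p of IL22 was 0.0286, the smallest possible, with an adjusted p of 0.44, and that of IL13 was 0.0857. The median of all genes was -0.04 without asthmatic donor 3 and -0.07 with total-count scaling, and the count at an unadjusted p under 0.05 was 3, 2 and 2 without healthy donors 1, 3 and 4.

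Over all donors, AMPK and CLTC were lower with exosomes in 7 of 7 pairs, with log2 changes of -0.26 (SE 0.12) and -0.26 (SE 0.16), where chance gives 1.56%, or 1.2 genes. Some of these changes were close to 0. AMPK ran from -0.62 in asthmatic donor 3 to -0.03 in healthy donor 4. CLTC ran from -1.16 in asthmatic donor 3 to -0.007 in healthy donor 2, whose cultures were read in different runs. CLTC was at -0.11 without asthmatic donor 3. Their exact sign-flip p was 0.0156, the smallest the sign patterns can give, with an adjusted p of 0.602. IL5 was at -0.68 (SE 0.24, n = 7 pairs), IFNG at -0.43 (SE 0.29), TBX21 at -0.38 (SE 0.26), IL13 at -0.33 (SE 0.27) and IL4 at -0.31 (SE 0.30). IL10 was at -0.25, FOXP3 at -0.23, GATA3 at -0.15, RORG at -0.07 and IL17 at 0.06, and ERRA, SIRT1 and PGC1A were at -0.25, -0.10 and -0.56. Without healthy donor 4, TBX21 was at -0.16, FOXP3 at 0.07 and IL17 at -0.02. Without asthmatic donor 3, GATA3 was at 0.03, ERRA at -0.07, SIRT1 at -0.02, PGC1A at 0.00, IL10 at -0.12 and RORG at -0.25, and without healthy donor 1 IL10 was at 0.01. Without asthmatic donor 1, IFNG was at -0.19, IL13 at -0.18 and IL4 at -0.10. In all, 13 of 15 named genes were turned or moved by over 1.5-fold by leaving out 1 donor. With limma 0 of 77 genes passed, the smallest adjusted p was 0.858, and 2 had an unadjusted p under 0.05, IL5 and NOX2, both lower. NOX2, within the lowest 25%, was at -1.02 (SE 0.39), lower in 5 of 7 pairs and above background in 9 of 14 libraries. It went from 14 to 2 counts in asthmatic donor 2 and from 9 to 1 in healthy donor 4, and was at 1 count in the untreated library of asthmatic donor 3. Of the Th2 genes 7 of 7 were lower, median -0.31, with a fry adjusted p of 0.521, and the smallest p adjusted over the list alone was 0.150. With precision weights from voom, added after the data were seen, 2 genes passed, IFNG and IL9, with a smallest adjusted p of 0.0216, in a range of 0.0216 to 0.986 over the alternatives. IFNG was above background in 6 of 14 libraries and lower in 5 of 7 pairs, and IL9 in 5 libraries and 6 pairs. Their changes were -1.86 and -1.98 in asthmatic donor 1, and -1.18 and -1.10 in healthy donor 2, whose pair is confounded with the run. The median of all genes, -0.11, was -0.04 without asthmatic donor 3, where 0 genes had an unadjusted p under 0.05, against 1 without healthy donor 2 and 4 without healthy donor 4.

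TUBB and RPL19 were the genes the authors scaled to, so that their joint change was held near 0 by the scaling. TUBB had a mean log2 change of 0.04 (SD 0.33, n = 7 pairs, exact two-sided sign-flip p = 0.766) and RPL19 one of 0.09 (SD 0.28, exact p = 0.469). ACTB was at -0.09 (exact p = 0.109) and PGK1 at -0.12 (exact p = 0.297). Without asthmatic donor 3, TUBB had a mean of -0.03. Across libraries, TUBB varied 6.54-fold and RPL19 5.48-fold, and TUBB rested on 1 count in the untreated culture of asthmatic donor 3.

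Asthmatic and healthy donors were next compared in untreated cultures, which concerns the state of cells cultured for 7 days without exosomes. Mean signals of the Th1, Th2, Th17 and regulatory cytokine genes named here were higher in asthmatic donors, with log2 differences of 3.51 for IFNG (SE 3.15, 3 against 4 donors), 2.98 for IL17 (SE 3.33), 2.37 for IL5 (SE 1.83), 2.02 for IL13 (SE 1.86), 1.78 for IL4 (SE 1.74) and 1.66 for IL10 (SE 2.18), while IL9 was lower at -0.79 (SE 1.70). The higher means rested on asthmatic donor 3, whose IFNG signal was 149308, against 51.45 and 6.44 in the other asthmatic donors and 11.0 to 113.7 in healthy donors. IL2 was 849192 in that culture and at most 114.2 in any library of the other donors. Both cultures of this donor exceeded all 12 other libraries for 32 genes, among them MYC, which drives cell growth, at 46659 and 39977, the glycolytic genes PKM2 at 64545 and 48409 and HK2 at 4925 and 4075, and TBX21 at 6999 and 5250. They lay below all 12 for c-MAF, ETS-1, HDAC1, PI3KD and TUBB. Of these, c-MAF and ETS-1 had 1 count each untreated and 9 and 10 treated, not above background in either culture. The 32 genes included RORG, at 1 count untreated, and SLC2A3, at 1 and 14 counts and above background in 0 libraries. Asthmatic donor 3 and healthy donor 4 were also the donors whose labels named no run.

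**Figure D3:**
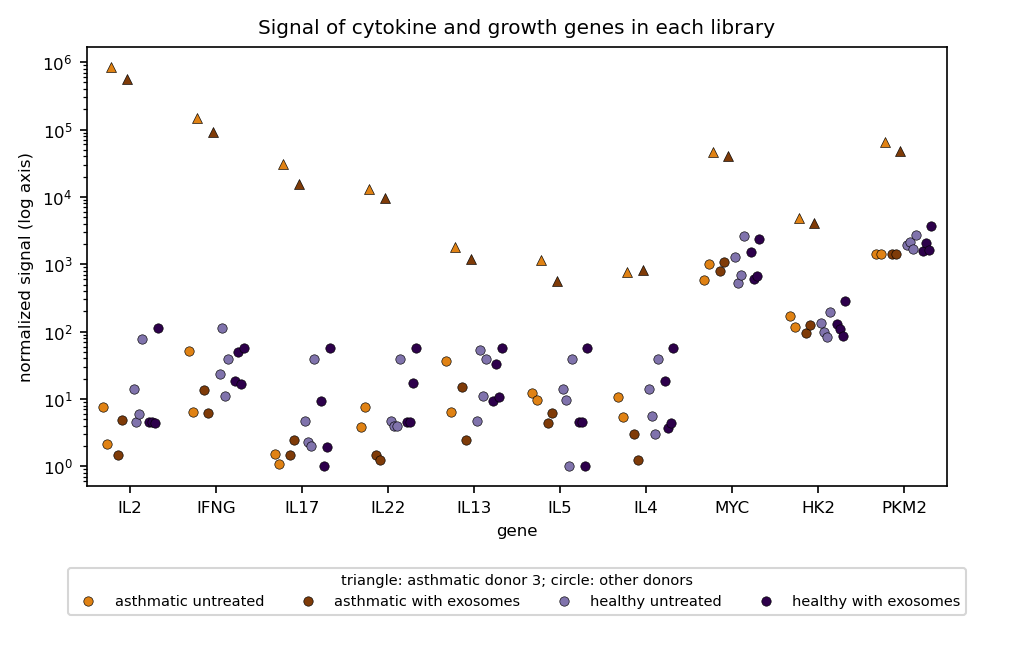
Normalized signal (log axis) of 10 cytokine and growth genes in each library, with 1 symbol per library, colours for the 4 groups and triangles for asthmatic donor 3. IL2 was 849192 and 568811 in the cultures of that donor and at most 114.2 in the other 12, and IFNG, IL17, IL22, MYC, HK2 and PKM2 were also highest there.

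Among the regulators, TBX21 differed by 1.83 (SE 1.83), GATA3 by 0.33 (SE 0.58), RORG by 0.02 (SE 0.95) and FOXP3 by -0.03 (SE 0.83), and among the mitochondrial genes PGC1A by 0.89, SIRT1 by 0.61 and ERRA by 0.59. Of these 13 lineage and mitochondrial genes, 10 turned direction without asthmatic donor 3, among them IFNG at -0.79, IL17 at -1.58, IL13 at -0.24, IL4 at -0.38, TBX21 at -0.53, GATA3 at -0.18 and ERRA at -0.20, while IL5 was at 0.16 and SIRT1 at 0.05. The glucose transporter gene GLUT1 at 1.01 (SE 0.58) and the sphingomyelinase gene SMPD1 at 1.23 (SE 0.61) were the 2 genes whose groups did not overlap, where chance gives 5.71%, or 4.4 genes. SMPD1 was at 1 count and GLUT1 at 2 counts in asthmatic donor 3, without which they were at 0.75 and 0.55. Of the Th17 genes 6 of 6 were higher, median 1.97, of the Th1 genes 5 of 6, median 1.94, and of the glycolysis genes 7 of 8, median 1.04. Leaving out asthmatic donor 3 made these 1 of 6, 2 of 6 and 4 of 8, with medians of -0.36, -0.30 and -0.19. The smallest fry adjusted p was 0.793, and 0 genes passed when adjusted over the list alone. With limma 0 of 77 genes passed, the smallest adjusted p was 0.943, 0 had an unadjusted p under 0.05, and the median 95% interval reached 1.97 to either side.

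The median difference of all genes, 0.32, was -0.29 without asthmatic donor 3, and with total-count scaling it was -0.47. Within the first run, with 2 asthmatic donors and 1 healthy donor, the median was -0.34 and IFNG was at -0.31, IL13 at 1.54 and TBX21 at 1.07. Between the libraries naming no run, 1 against 1, the median was 0.73 and IFNG was at 11.87, IL13 at 5.51 and TBX21 at 5.16, and 38 of 77 genes had the same sign in both. With the run as a block, limma called 0 genes, 6 at an unadjusted p under 0.05, with a smallest adjusted p of 0.580.

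In exosome-treated cultures, c-MAF, a transcription factor of Th2 and follicular helper cells, was lower in asthmatic donors at -1.47 (SE 0.85, 3 against 4 donors). It was the 1 gene whose groups did not overlap, where chance gives 5.71%, or 4.4 genes. IFNG differed by 2.74 (SE 3.16), IL17 by 2.74 (SE 3.14), IL5 by 1.86 (SE 1.89), TBX21 by 1.79 (SE 1.75), IL10 by 1.41 (SE 1.98), IL13 by 0.87 (SE 1.92) and IL4 by 0.57 (SE 2.13). RORG was at 0.40, FOXP3 at 0.26 and GATA3 at 0.06, and SIRT1, ERRA and PGC1A were at 0.33, 0.24 and -0.73. These means rested on asthmatic donor 3, without which 11 of the 14 named genes turned direction, with IFNG at -1.65, IL17 at -1.39, IL5 at -0.31, TBX21 at -0.57, IL10 at -0.89, IL13 at -1.57, IL4 at -2.13 and RORG at -0.97, and c-MAF was at -0.84. Without healthy donor 4 c-MAF was at -0.87 and PGC1A at 0.36. Of the glycolysis genes 8 of 8 were higher, median 1.04, with a camera adjusted p of 0.00853 and a preset correlation. This list had an adjusted p = 0.749 with an estimated correlation and 0.865 with fry. When asthmatic donor 3 was left out, 2 of 8 glycolysis genes were higher, median -0.28. Of the Th17 genes 6 of 6 and of the Treg genes 5 of 5 were higher, but 0 of 6 and 1 of 5 without that donor, and 0 genes passed when adjusted over the list alone.

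Limma called 0 of 77 genes between treated cultures, the smallest adjusted p was 0.974, and 0 had an unadjusted p under 0.05. The median difference was 0.10, and -0.30 without asthmatic donor 3. Within the first run, with 2 donors of each group, the median was -0.10 and c-MAF was at -0.31, and between the libraries naming no run, 1 against 1, the median was -0.15 and c-MAF was at -4.52, with 27 of 77 genes of the same sign. With the run as a block 0 genes passed, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.742.

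Treated asthmatic cultures were last compared with untreated healthy cultures, the control named in the design text. IL17 differed by 2.90 (SE 3.08, 3 against 4 donors), IFNG by 2.64 (SE 3.22), TBX21 by 1.42 (SE 1.86), IL5 by 1.40 (SE 1.82), IL10 by 1.26 (SE 2.01), IL13 by 1.04 (SE 1.98) and IL4 by 0.78 (SE 2.09). SIRT1 was at 0.35, RORG at 0.17, ERRA at 0.14, GATA3 at 0.03, FOXP3 at -0.09 and PGC1A at -0.60. When asthmatic donor 3 was left out, 11 of these 13 genes turned direction, with IL17 at -1.23, IFNG at -1.75, TBX21 at -0.94, IL5 at -0.77, IL10 at -1.04, IL13 at -1.41 and IL4 at -1.92. Glycolysis genes were higher in 8 of 8 cases, median 1.00, with a camera adjusted p of 0.0218 and a preset correlation. This list had an adjusted p = 0.690 with an estimated correlation and 0.823 with fry, and 0 genes passed when adjusted over the list alone. In this list 2 of 8 genes were higher without asthmatic donor 3, median -0.16. With limma 0 of 77 genes passed, the smallest adjusted p was 0.983, 0 had an unadjusted p under 0.05, and the groups did not overlap for 0 genes, where chance gives 5.71%. The median difference was 0.10, and -0.36 without asthmatic donor 3. Within the first run, 2 against 1 donors, the median was -0.39, between the libraries naming no run it was 0.11, and 40 of 77 genes had the same sign. With the run as a block 0 genes passed, 7 had an unadjusted p under 0.05, and the smallest adjusted p was 0.375.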

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

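The counts over other divisions of the donors were planned, and the other tests here, of the patterns in asthmatic donor 3 and of the cytokine genes, were chosen after the results were seen.

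Both cultures of asthmatic donor 3 stood apart, with 32 genes above and 5 below all 12 other libraries. A single scaling factor per library was argued against, since the count ratio of IL2 to RPL19, in which a factor cancels, was at least 967 times that of any other library with its IL2 count raised to background, and 20 of the 32 genes had ratios to RPL19 above all others in this way. As to a difference shared by the asthmatic donors, 0 of the 32 genes were higher in all libraries of asthmatic donors 1 and 2 than in those of healthy donors 1 to 3. This argues against it for genes above background in all 10 of these libraries, such as MYC, HK2 and PKM2. It cannot decide for IL2, IL4, IL10, IL17, IL21 and SLC2A3, which were above background in 0 of the 10. Of 10 cytokine genes, 9 lay above all other libraries in both cultures, so stimulation of these cells may be a candidate explanation, but with 1 donor, handling, run and donor cannot be told apart.

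IL4, IL5, IL13 and IL22 were lower with exosomes in asthmatic donors. Counts at background stay open as an explanation, since 2 of 16 values of these genes in asthmatic donors 1 and 2 were above background. A shift in scale of the whole library cannot be told apart from the rest, since the 4 genes were picked for their changes and lie near background. Their median change was -0.99, against -0.23 (SD 0.43) for the other 73 genes. An effect of the exosomes on these genes also stays open, and the test of the difference from healthy donors did not call any of them (limma adjusted p of 0.588 to 0.760).

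Many genes were lower with exosomes in asthmatic donor 3, whose untreated library had the largest signal per count of the 14. The 22 genes at 1 count there had a median change of -0.83, against -0.50 for the 55 others, a difference of -0.33 (one-sided permutation p = 0.0131 over genes, which are not independent replicates). Of the 11 drops beyond -1.5, 9 were in genes at 1 count, so values held up at a single count may account for the size of these drops, but 16 of 22 genes at 1 count were lower, against 44 of the 55 others. TUBB was also at 1 count there (95% Poisson interval 0.0253 to 5.57), against 23 in the treated library. The interval takes this 1 as a count that was read. Since 22 genes and all negative probes were at 1 count there, it may be a lowest listed value, for which the interval would not hold. With RPL19 alone as reference the median of the genes not at 1 count was -0.18. The 95% interval of -0.29 to -0.07 covers the counting error of RPL19 only, not the spread of the genes or between cultures. Whether the scaling or the exosomes lowered the genes not at 1 count cannot be told apart, because the scaling factor rests on that TUBB count.

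For exosomes in asthmatic donors, 2 of the 4 sign patterns of the pairs gave at least the real 8 genes at an unadjusted p under 0.05, and the highest other gave 8. In healthy donors 8 of 8 patterns gave at least the real 0, and the highest other gave 3. In both groups the patterns were too few for a share under 0.05. For the difference of the effects, 2 of 35 divisions of the donors gave at least the real 6 genes, with a highest other of 8, and over all donors 40 of 64 patterns gave at least the real 2, with a highest other of 11, so chance was not excluded. For asthmatic against healthy donors, 35 of 35 divisions gave at least the real 0 genes in untreated cultures, treated cultures and across them, with highest others of 31, 28 and 29. A real count of 0 is reached by every division or pattern, here and in healthy donors, so these shares say nothing about chance. The division with the highest count in each of these comparisons set healthy donor 1, asthmatic donor 3 and healthy donor 4, which had the largest signals per count, against the rest. It was picked as the highest of 35, so its count of 31 in untreated cultures does not by itself show a structure apart from disease. In any division other than the real one, at most 21 genes passed the adjusted threshold in untreated cultures, 0 in treated cultures and 12 across them.

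IL22 in the untreated culture of healthy donor 4 was 38.96, far from 3.96 to 4.70 in the other 3, and stood for 1 count, not above background. c-MAF in the treated culture of healthy donor 4 was 1599 (28 counts), far from 279.4 to 346.6 in the other 3. Of 70 such groups examined, these 2 had a library far from the rest, where chance gives about 5%, or 3.5. LKB1 was lower with exosomes in 3 of 3 asthmatic donors (-0.38 to -0.06) and higher in 4 of 4 healthy donors (0.02 to 0.55), a difference of -0.48 with a limma adjusted p of 0.760, and 6 of 7 donors kept their direction after centring on the median gene. LKB1 had 1 count in the untreated library of asthmatic donor 3 and 2 counts in each library of healthy donor 4, whose 0.55 was the change in signal per count. Of 77 genes, chance gives 1.2 with such opposite directions, and LKB1 was singled out after its values were seen.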

How the results depend on the processing

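Over 24 alternative settings, 148 of 149 counts of genes past the threshold were 0, as in the results reported. Over all donors, precision weights from voom, chosen after seeing the data, gave 2 genes, and the cause was not tested. For the gene lists in asthmatic donors, centring on the median gene gave 1 list, Th2, with a fry adjusted p of 0.0207. The cause was not tested, and the range over the alternatives was 0.0207 to 0.462. Camera with a preset correlation gave 1 list, glycolysis, in treated cultures and 1 in treated asthmatic against untreated healthy cultures. With an estimated correlation camera gave 0 lists. Leaving out each donor in turn gave 0 to 0 genes and 0 to 0 lists in each comparison, and a TUBB change of -0.03 to 0.13 and an RPL19 change of 0.01 to 0.15. Without the replicate block, the effect of exosomes in asthmatic donors gave 0 genes, 1 at an unadjusted p under 0.05, against 8 with the donors paired. The smallest adjusted p ranged from 0.0628 to 0.999 in asthmatic donors, 0.317 to 1 in healthy donors and 0.109 to 0.988 for the difference. Also chosen after seeing the data were the filter to genes above background in at least 7 libraries, leaving out the 4 libraries naming no run, raising values to the largest step, and scaling to RPL19 alone or to the total count without 4 genes. These gave 0 genes in each comparison. IL13 was lower in asthmatic donors in 21 of 21 settings, with changes of -1.17 to -0.20, and was above background in 6 of 14 libraries.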

Other observations

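Apart from exosomes and disease, genes of lipid metabolism varied between donors. Among the 5 donors with named runs, 53 genes were above background in all 10 libraries, with a median range between donor means of 0.86 on the log2 scale and a median change with exosomes of 0.13 in size. The SD between donors exceeded the SD of the changes with exosomes for 42 of the 53. The sterol synthesis gene LSS had a 5.11-fold range of donor means, the lipase gene ATGL a 4.29-fold range and the sterol regulator SREBP2 a 3.72-fold range. These genes were chosen after their values were seen.

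In healthy donor 1, LSS was 418.3 and 452.9 and SREBP2 1222 and 1077 without and with exosomes. In the other 8 libraries of these donors, LSS was 83.2 to 184.7. The total counts of healthy donor 1, 16842 and 16280, were the lowest of these donors.

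The positive control probes of the untreated library of asthmatic donor 3 had a geometric mean of 38.3, against 448.7 to 919.4 in the other 13 libraries. TUBB had 1.36 and 2.29 counts per 1000 of RPL19 in this donor, 4.52 and 4.57 in healthy donor 4, and 11.7 to 48.0 in the other 10 libraries. Correlations between libraries over genes, which are not independent replicates, were 0.942 to 0.995 within donors, 0.808 to 0.983 between different donors other than asthmatic donor 3, and 0.12 to 0.321 between asthmatic donor 3 and the other donors.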
